A study of Rattus norvegicus with 6 samples.

How the data were processed

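RNA from H9c2 cells, a line derived from embryonic rat heart, was measured by RNA sequencing in 6 libraries. All cells went through simulated ischemia-reperfusion (sIR). Per the labels' protocols, cells were kept in an acidic buffer of pH 6.2 in a chamber flushed with 95% nitrogen and 5% carbon dioxide for 30 min, which then stayed closed for 1.5 to 3.5 h. The protocols also give 10% serum, the same for all 6 libraries. Libraries were made from 1 ug of total RNA with an Illumina TruSeq kit, per the labels' protocols. The labels put 3 libraries in a control adenovirus group and 3 in a group with an adenovirus for PERK. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

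The authors' deposited table gives estimated counts per gene for 26126 entries, as whole numbers, and they were used as deposited. The submitters' processing notes name Bowtie 0.12.2 and the mouse build mm9, while the entries carry rat gene names. The build behind the counts and the counting program are not given in the sources used here. The deposited normalized signal of each library equals its counts divided by 1 size factor, as tested on the file, and was not used in any test. The deposited table also holds the authors' log2 fold changes, their standard errors, a test score, p-values and adjusted p-values. Their mean expression column is not the mean of the 6 normalized columns, and the reason is not given in the sources used here. A second table has 6 columns of per-sample values whose names match no label, and it was not used.

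Total counts ranged from 77923398 in control replicate 3 to 119087414 in PERK replicate 2. Low counts fell near multiples of about 6 in every library (period 5.8 to 6.05), so the number of independent fragments behind a count is unknown and may be smaller than the count. Lower limits for a gene listed at 0 were set at 18 counts per library, which is 3 steps of 6 counts. Intervals and limits cover counting error only.

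The comparison was PERK-labelled against control libraries, 3 against 3, in edgeR 4.0.16 (R 4.3.3). Counts were scaled by TMM and filtered with filterByExpr (minimum count 10), which left 14488 entries. A quasi-likelihood fit without robust estimation was tested with glmQLFTest, group as the only term. P-values were adjusted by Benjamini-Hochberg at 0.05. Standard errors of log2 fold changes were computed from the fold change and the F statistic. Expression is given as CPM of the TMM-scaled totals, with mean ± SD over 3 libraries. Of the entries, 37 are mitochondrial and 1090 are olfactory receptor genes.

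Before the data were examined, 29 gene lists were fixed from textbook knowledge of PERK, ischemia, mitochondria, adenoviral infection, H9c2 cells and other cell types. The 26 lists with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM (prior count 2), with an inter-gene correlation preset at 0.01, and again with the correlation estimated. Adjustment was over the 26 lists. With the preset correlation 9 lists passed 0.05, and with an estimated correlation 0 did. With an estimated correlation, camera's unadjusted p was 0.011 for immediate early genes, 0.0172 for sterol synthesis, 0.0357 for ATF4 targets and 0.0421 for cell cycle genes, and above 0.05 for the other lists. The fry test, which asks whether the members of a list move on balance 1 way, passed 11 lists, and its mixed form, which asks for change in either direction, passed 13. Adjusted p-values "over the list alone" use the members of that list only. The lists of endothelial, leukocyte and epithelial markers had too few tested members.

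Genes named in the text follow a rule fixed beforehand. It takes Eif2ak3, the other eIF2 kinases, Atf4 and Ddit3. It adds the 8 largest rises, the 8 largest falls and the 4 smallest p-values among changed genes whose groups do not overlap, with an ordinary symbol and at least 5 CPM in the higher group. It further takes up to 3 changed members of each list, or its 2 most abundant members where none changed. The fixed rule asked for 5 FPKM, and CPM replaced it because FPKM was not used. Other genes named were chosen after their values were seen, and are said to be so. Some genes that the rule takes are not reported here, and they stay in the tests and counts. Gene neighbours came from a RefSeq table of the GRCr8 assembly, used only for names and neighbours.

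The steps were tested on simulated data. Counts for the 14488 tested entries were drawn from the real means, and 14034 passed the filter again. The 200 changed genes were chosen among those with a mean of at least 5 CPM. Draws were independent and had no steps of 6 counts, so the recovery below holds for such data only. edgeR recovered 4 of 50 genes changed 1.2-fold, 32 of 50 at 1.5-fold, 46 of 50 at 2-fold and 50 of 50 at 4-fold. Of its 137 calls, 5 were false. False calls numbered 45 with DESeq2, 17 with a replicate block and 3 with limma voom. Most differences reported here are under 1.5-fold, where many real changes would be missed.

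Alternatives fixed beforehand were a replicate block, DESeq2 1.42.0, limma voom, DESeq2 size factors, no filter, a stricter filter (10 counts in every library of 1 group), each library left out, scaling without the 50 most abundant entries or without mitochondrial entries, a 2-fold limit, and only rows with a gene symbol. A robust fit, counts divided by 6, and leaving out all-or-none genes (under 0.1 CPM in 1 library and at least 5 CPM in another) were added after seeing the data. Pairs of libraries of 1 group differed more than independent counts would (chi-square over degrees of freedom 119 to 254). That ratio includes all-or-none entries and counts in steps of about 6, so it cannot show that the libraries are separate replicates. All 6 were kept as separate replicates. Figures were drawn with matplotlib.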

Results

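The data are RNA-seq counts from H9c2 rat cardiac cells after sIR, 3 libraries with a control adenovirus and 3 labelled as PERK overexpression. PERK, encoded by Eif2ak3, is an endoplasmic reticulum kinase that phosphorylates eIF2 alpha and lowers general translation while raising ATF4. The comparison asks how gene expression after sIR differs when PERK is overexpressed. Total counts were 111052659, 81000592 and 77923398 in control replicates 1 to 3, and 100816534, 119087414 and 89798433 in PERK replicates 1 to 3. Entries above 0 numbered 19287 in control replicate 3 and 15377 to 16685 in the other 5 libraries. Olfactory receptor genes, used mainly in the olfactory epithelium, were above 0 for 45.4% of 1090 genes in control replicate 3 and for 6.24% to 14.5% in the others. Mitochondrial entries took 16.5% to 17.7% of counts and the 7SL RNA 6.17% to 9.37%.

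**Figure D1:**
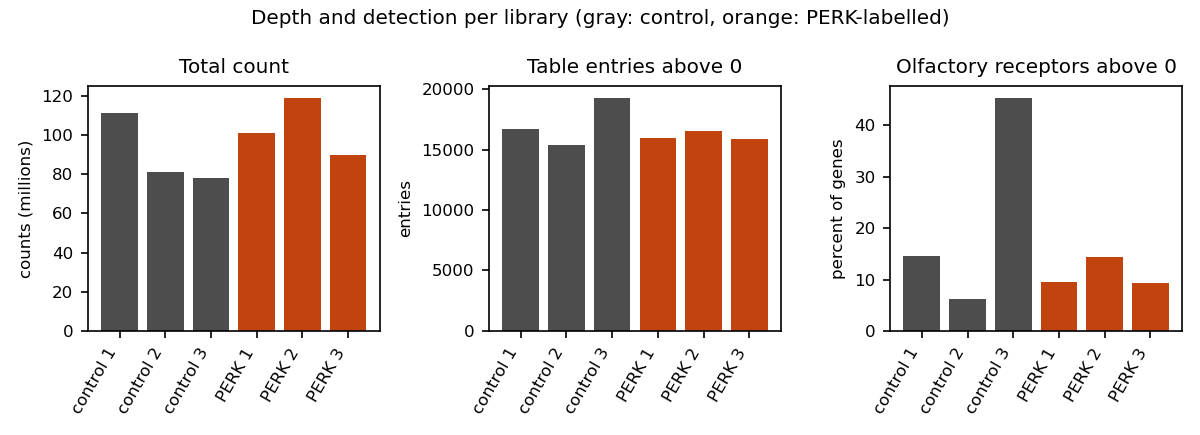
Total counts, number of table entries above 0 and percent of olfactory receptor genes above 0, as 1 bar per library, with control libraries in gray and PERK-labelled libraries in orange. Control replicate 3 has the smallest total, 77923398, and the largest share of olfactory receptor genes above 0, 45.4%.

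Eif2ak3 was not higher in the libraries labelled PERK. Its level was 26.4, 26.9 and 24.0 CPM in control replicates 1 to 3 and 26.5, 26.5 and 26.0 CPM in PERK replicates 1 to 3. The log2 fold change was 0.03 (SE 0.06, edgeR adjusted p = 0.887), and it was -0.02 without control replicate 3. A transgene whose sequence differs from the rat gene may be missed by this count, which was not tested. Eif2ak3 thus does not check the labels, and every direction below is drawn from the labels alone. The other eIF2 kinases Eif2ak1, Eif2ak2 and Eif2ak4 had log2 fold changes of 0.12, -0.03 and 0.04, none past the test. Atf4, the transcription factor translated when eIF2 alpha is phosphorylated, was 409 ± 7.95 CPM in control and 450 ± 15.8 CPM in PERK-labelled libraries (SD, n = 3; log2 fold change 0.14, edgeR adjusted p = 0.19). Ddit3, which encodes CHOP, a factor of prolonged stress, was 21.5 ± 0.997 and 21.5 ± 2.88 CPM.

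Genes that rose in the PERK-labelled libraries included Ppp1r15a, Fos, Hspa1b and Hmgcs1, and genes that fell included Igfbp5, Cpt1a and Hist1h1d. Ppp1r15a, which encodes GADD34, the phosphatase subunit that reverses eIF2 alpha phosphorylation, rose from 75.4 ± 0.31 to 120 ± 4.54 CPM (log2 fold change 0.67, SE 0.04). Fos, an AP-1 transcription factor, rose from 12.97 ± 1.76 to 30.2 ± 0.742 CPM (log2 fold change 1.22, SE 0.09). Scd, a stearoyl-CoA desaturase, rose by 0.96 on the log2 scale (SE 0.11), and Igfbp5, an insulin-like growth factor binding protein, fell by 0.58 (SE 0.04). Cpt1a, which brings fatty acids into mitochondria, fell from 42.6 ± 0.993 to 31.1 ± 1.65 CPM.

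Of 14488 entries tested, 61 changed, 45 higher and 16 lower. That is 0.421% of the tested entries, and 1627 had an unadjusted p under 0.05. The median size of the 61 log2 fold changes was 0.38. Fold changes of 2 or more were found for Fos, Rtkn and LOC100910245, the last chosen after its values were seen. Rtkn had 0 counts in all 3 control libraries and 1276, 1694 and 1188 in the PERK-labelled ones, at least 57.9-fold higher against a limit of 18 counts per library (edgeR adjusted p = 4.6e-05). It is 1 of 80 entries near 0 in some libraries and well expressed in others, and 76 of these 80 differ within a group. LOC100910245 stood at 4.53, 3.79 and 2.70 CPM in control replicates 1 to 3 and at 0, 0.05 and 0 CPM in PERK replicates 1 to 3. LOC100910245 was thus near 0 in some libraries as well, and is not among the 80 because no library reached 5 CPM.

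**Figure D2:**
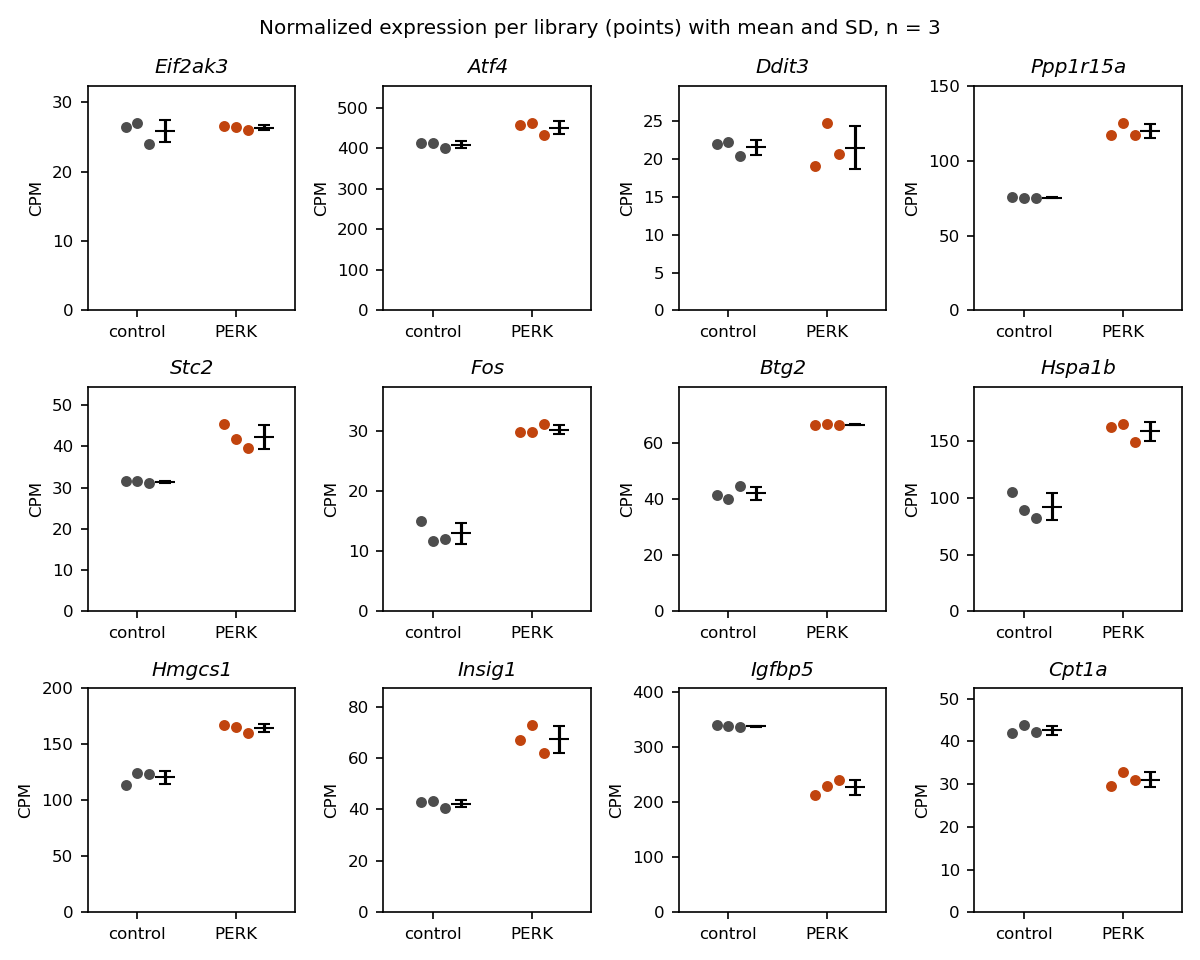
CPM of 12 genes in each library, with control libraries in gray and PERK-labelled libraries in orange; the horizontal mark and bar beside them give the mean and SD of 3 libraries. Eif2ak3 and Ddit3 overlap between groups, while Ppp1r15a, Fos, Hmgcs1 and Igfbp5 do not.

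Among the largest rises were also Hspa1a (0.80, SE 0.11) and Hspa1b (0.79, SE 0.09), inducible HSP70 genes that share reads with each other and are uncertain as single genes. Insig1, which holds back sterol synthesis, rose by 0.67 (SE 0.06), and Btg2, an anti-proliferative gene and p53 target, by 0.66 (SE 0.05). The smallest p-values belonged to Rtkn, Ppp1r15a, Btg2 and Fos, with edgeR adjusted p from 4.6e-05 to 0.0032. The largest falls after Igfbp5 included Islr (-0.55), Olfml2a (-0.43) and B4galt5 (-0.36), with edgeR adjusted p of 0.0094, 0.0137 and 0.0344. Hist1h2ail1 (-0.84), Hist1h1b (-0.50) and Hist1h1d (-0.47) also fell. They are uncertain as single genes, because sharing of reads among histone genes was not tested.

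Targets of ATF4 passed camera upward with the preset correlation. Of 33 tested members, 2 rose over all genes and 14 when adjusted over the list alone, with none lower, and the median log2 fold change was 0.14 (camera adjusted p = 4.9e-08, and adjusted p = 0.274 with an estimated correlation). The 2 became 1 without any single library but PERK replicate 3, and 6 with the robust fit. The 2 were Ppp1r15a and Stc2, a secreted stress glycoprotein, which rose from 31.4 ± 0.206 to 42.2 ± 2.93 CPM. Cytosolic tRNA synthetases, many of them ATF4 targets, passed camera upward with the preset correlation (median 0.08, camera adjusted p = 2.1e-04). Of 20 members, 0 passed the test over all genes and 2 over the list alone. With an estimated correlation of 0.19 camera gave adjusted p = 0.294, so a rise of the list stays open. Eprs and Aars, the most abundant, had log2 fold changes of 0.15 and 0.06. The eIF2 kinases and feedback genes passed camera with 1 of 14 members higher, Ppp1r15a, both over all genes and over the list alone (median 0.05, camera adjusted p = 0.0389, adjusted p = 0.294 with an estimated correlation). Endoplasmic reticulum chaperones passed with 0 of 26 members changed by either adjustment (median 0.04, camera adjusted p = 0.0389, adjusted p = 0.596 with an estimated correlation), and Calr and Hsp90b1 had log2 fold changes of 0.03 and 0.01. The call for the kinase list ended without control replicate 1 (adjusted p = 0.05001), control replicate 3 (0.177) or PERK replicate 3 (0.109), and that for the chaperones without control replicate 3 (0.314) or PERK replicate 1 (0.192). The chaperone median was 0.028 without control replicate 3 and 0.023 without PERK replicate 1. Both ended with a stricter low-count filter (adjusted p = 0.0545 each), and the fry test, which does not compare a list with other genes, did not pass the chaperones (adjusted p = 0.215, mixed form 0.0565).

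All 16 tested immediate early genes lay above 0. Of them 4 rose over all genes and 8 over the list alone, with a median of 0.37 (camera adjusted p = 9.6e-12, adjusted p = 0.223 with an estimated correlation). The 4 became 2 without control replicate 1 and 1 without any other single library. Besides Fos the 4 included Dusp1, a MAP kinase phosphatase (0.38, SE 0.04), and Egr1 (0.55, SE 0.06). Heat shock genes passed camera upward with the preset correlation (median 0.08, camera adjusted p = 0.00255). With an estimated correlation of 0.12 camera gave adjusted p = 0.294, so a rise of the list stays open. Of 16 members, 3 were higher over all genes and 4 over the list alone. The 3 became 3, 0 and 1 without control replicates 1, 2 and 3 and 0 without any 1 PERK library. Dnajb1, an HSP40 co-chaperone, rose from 109 ± 4.87 to 139 ± 1.17 CPM beside Hspa1a and Hspa1b.

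Sterol synthesis had the smallest camera p of the 26 lists with the preset correlation, while with an estimated correlation immediate early genes had a smaller one (unadjusted p = 0.011 against 0.0172). All 20 members lay above 0, between 0.20 and 0.67, and 8 rose over all genes and 17 over the list alone (median 0.37, camera adjusted p = 1.5e-20, adjusted p = 0.223 with an estimated correlation). The 8 became 3 to 5 without 1 control library, 1, 3 and 5 without PERK replicates 1, 2 and 3, and 14 with the robust fit. Hmgcs1, an early enzyme of the mevalonate pathway, rose from 121 ± 5.66 to 164 ± 3.46 CPM, and Insig1 from 42.2 ± 1.32 to 67.3 ± 5.34 CPM.

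Cell cycle genes passed camera downward with the preset correlation, with 27 of 31 below 0. None changed over all genes and 9 fell over the list alone (median -0.09, camera adjusted p = 2.8e-05, adjusted p = 0.274 with an estimated correlation). The 9 became 2, 7 and 1 without control replicates 1, 2 and 3 and 4, 4 and 1 without PERK replicates 1, 2 and 3. Mki67 and Rrm1, the most abundant, had log2 fold changes of -0.12 and -0.10. Matrix and fibroblast genes passed camera upward, with 11 members above 0 and 8 below. Of 19 members, 3 rose over all genes and 8 over the list alone (median 0.06, camera adjusted p = 0.0051, adjusted p = 0.308 with an estimated correlation). That call ended without control replicate 1 (adjusted p = 0.05001) or PERK replicate 3 (0.0883). Over the 16 alternatives run on lists the median ranged from 0.021 to 0.091. Fry did not pass this list upward (adjusted p = 0.0631), though its mixed form did (8.8e-05). The 3 became 2, 2 and 0 without control replicates 1, 2 and 3 and 0, 1 and 0 without PERK replicates 1, 2 and 3. The 3 were Cyr61 (0.32), Ctgf (0.36) and Thbs1 (0.18), which encode secreted matrix proteins.

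No list of mitochondrial genes passed camera with the preset correlation and the low-count filter. The nuclear genes of complex I (35 tested, median 0.01), complexes II and III (13, 0.0021), complex IV (11, 0.02) and complex V (15, 0.02) had 0 changed members, with camera adjusted p of 0.872, 0.845, 0.683 and 0.653. Ndufv1, Uqcrc2, Sdhc, Cox6a1, Cox4i1, Atp5b and Atp5a1 had log2 fold changes between -0.02 and 0.14. The 12 mitochondrially encoded genes had a median of -0.05 (camera adjusted p = 0.639), with Mt-co1 at 0.08 and Mt-co2 at -0.06. The mitochondrial ribosome (74 tested, median -0.01) and the mitochondrial unfolded protein response (13, 0.06) had 0 changed members and camera adjusted p of 0.977 and 0.0553. Mrpl17, Mrpl12, Hspd1 and Hspa9 were at 0.12, -0.05, 0.05 and 0.21. In the tricarboxylic acid cycle list (15, median 0.04, camera adjusted p = 0.125), Idh2 was at -0.01. In fatty acid oxidation (20, median -0.05, camera adjusted p = 0.683) Cpt1a was the 1 changed member over all genes and over the list alone. The median of that list was -0.019 without PERK replicate 1 and -0.025 without control replicate 3. The fry test passed the mitochondrial unfolded protein response (adjusted p = 0.0392) and the tricarboxylic acid cycle (0.0433), both upward, and its mixed form passed fatty acid oxidation (adjusted p = 4.3e-04). Without the low-count filter camera also passed the mitochondrial unfolded protein response (adjusted p = 0.0144) and the tricarboxylic acid cycle (0.0435). With an estimated correlation both had camera adjusted p = 0.232 in that fit.

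The other lists did not pass camera with the preset correlation and the low-count filter. The cytosolic ribosome had 1 changed member of 92, Rps16 (0.52), which has many near-identical copies and is uncertain (camera adjusted p = 0.872). NRF2 antioxidant genes, with 0 of 25 changed, held Prdx1 at 0.04 and Fth1 at 0.08 (camera adjusted p = 0.95). Hypoxia and glycolysis genes, with 0 of 24 changed, held Aldoa at 0.10 and Eno1 at 0.09 (camera adjusted p = 0.0943). Interferon response genes (0 of 21 changed, Ifi27 0.02) and NF-kB inflammatory genes (0 of 16 changed, Csf1 -0.08, Icam1 0.13) had camera adjusted p of 0.424 and 0.289. Autophagy genes (0 of 15 changed, Sqstm1 -0.08, Gabarap -0.0084) had 0.683. Of 15 p53 targets Btg2 was the 1 changed over all genes, while over the list alone 4 rose and 1 fell (camera adjusted p = 0.421). Of 17 striated muscle genes 1 fell over all genes, Myog, the myogenic factor myogenin, from 486 ± 10.2 to 400 ± 9.25 CPM, and over the list alone 1 rose and 1 fell (camera adjusted p = 0.492). In the antioxidant, hypoxia, striated muscle, cytosolic ribosome, mitochondrial ribosome and complex II and III lists, the median, the mean and camera's direction did not all share a sign. Fry passed hypoxia and glycolysis genes (adjusted p = 0.0392) and p53 targets (0.0414), both upward, and its mixed form passed both of these, NF-kB inflammatory genes (0.00467) and striated muscle genes (0.00356). Without the low-count filter camera passed hypoxia and glycolysis genes too (adjusted p = 0.0435, but 0.232 with an estimated correlation).

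Few markers of other cell types were tested, and none changed over all genes with edgeR. Tek, the only tested marker of 7 for endothelium, was 1.40 ± 0.145 CPM in control and 0.792 ± 0.134 CPM in PERK-labelled libraries (log2 fold change -0.82, edgeR adjusted p = 0.225); the authors' deposited table gives it -0.82 with adjusted p = 0.0251. Of 9 leukocyte markers 4 were tested, with Cd14 at 9.17 ± 1.82 and 9.22 ± 0.509 CPM and Csf1r at 0.748 ± 0.283 and 0.898 ± 0.0358 CPM. Of 7 epithelial markers 3 were tested, with Krt8 at 39.4 ± 0.581 and 41.3 ± 0.383 CPM and Krt7 at 11.7 ± 1.85 and 12.3 ± 0.336 CPM.

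**Figure D3:**
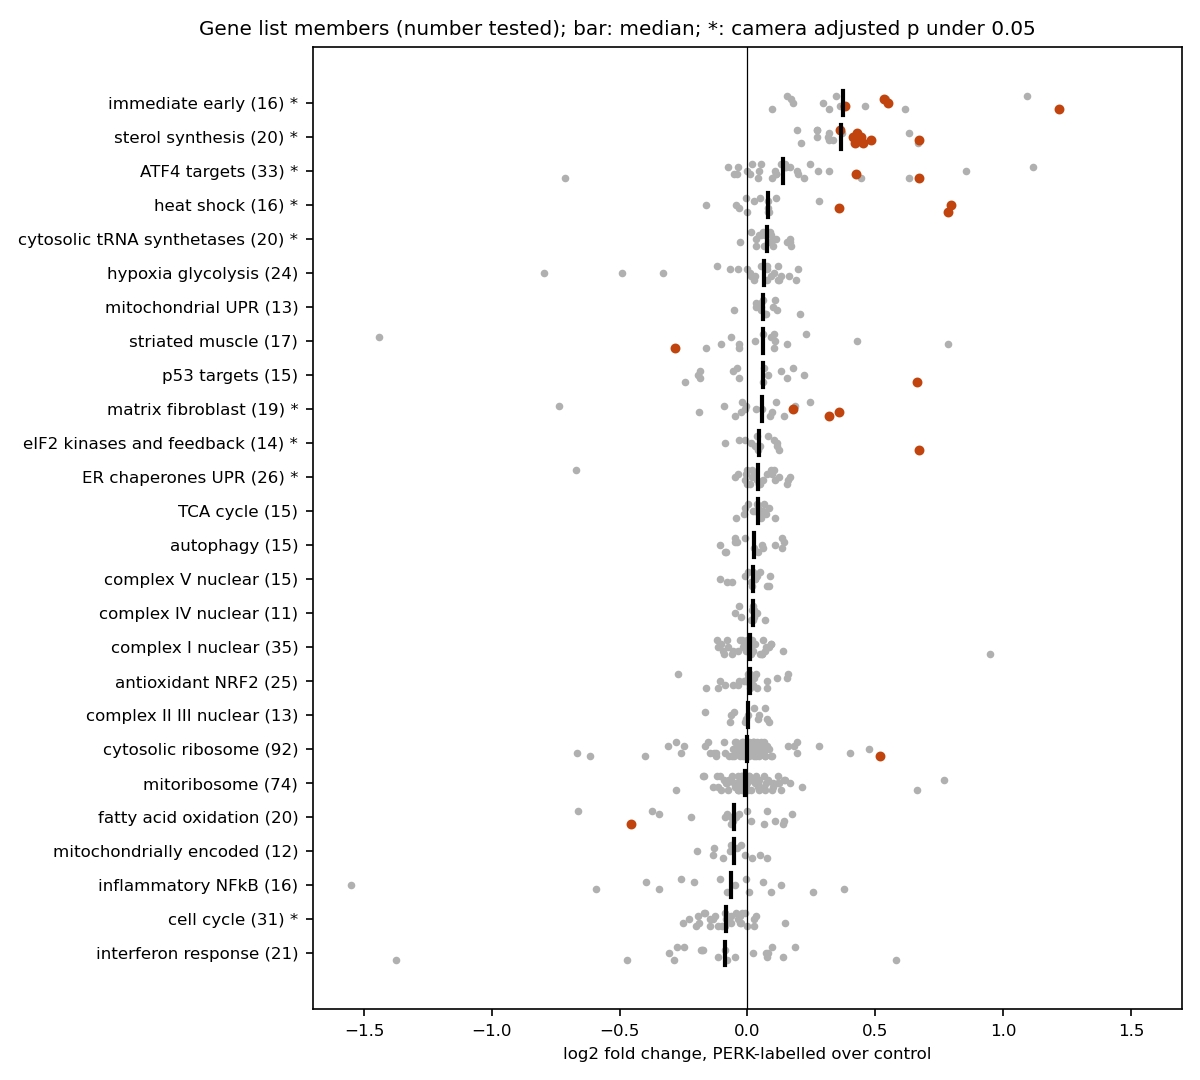
Log2 fold changes of the tested members of 26 gene lists, PERK-labelled over control, as points, with orange points changed over all genes and black bars at list medians. Immediate early and sterol genes have the highest medians, both 0.37, and 0 of the 26 lists pass camera with an estimated correlation.

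The number of calls fell whichever library was left out. Each such fit has fewer libraries and so less power. That loss was not told apart from the part played by the library left out. The groups did not separate on the first principal component (32.8% of variance), and 18.2% of tested entries had groups that do not overlap, against 10% by chance. Without control replicates 1, 2 or 3 the calls numbered 38, 26 and 23, and without PERK replicates 1, 2 or 3 they numbered 12, 21 and 14.

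The authors' deposited table lists 396 entries with adjusted p under 0.05, 125 higher and 271 lower. Of these, 214 have all 6 counts under 50, and 191 of the 214 are lower. The authors' deposited table, which holds the same counts, shares 47 of the 61 changed entries and gives Eif2ak3 a log2 fold change of 0.03. All 47 have the same sign, which the shared counts nearly fix. Of the 14 not shared, Rtkn has no adjusted p there, and Islr, Egr1, Thbs1 and Rps16 have 0.0571, 0.135, 0.498 and 0.895. DESeq2 run here on these 6 libraries called all 61. The authors' fit thus differed from that one, and how it differed is not given in the sources used here.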

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

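The robust fit, division by 6 and removal of all-or-none genes were chosen after seeing the data; the other alternatives were fixed beforehand. All 61 changed entries kept their sign in every alternative that tested them. The groups did not overlap for any of the 61, so a reversal on the same libraries was hardly possible. The 61 calls (45 higher, 16 lower) became 19 (12 and 7) with a replicate block, 357 (226 and 131) with DESeq2, 110 (83 and 27) with limma voom, 94 (63 and 31) without a filter, 92 (61 and 31) with a stricter filter, 132 (94 and 38) with the robust fit, 93 (63 and 30) with counts divided by 6, and 3 with a 2-fold limit. Only rows with a gene symbol gave 90 (63 and 27), and the all-or-none removal gave 83 (59 and 24). DESeq2 size factors gave 60 and the scalings without abundant or mitochondrial entries 59 and 60. Leaving out 1 library gave 12 (without PERK replicate 1) to 38 (without control replicate 1), with 7 to 23 higher and 4 to 15 lower. The share of calls that were higher was 63.2% with the block, 63.3% with DESeq2 and 52.2% to 71.4% with 1 library left out. Of 26 named called genes, 5 (Rtkn, Ppp1r15a, Btg2, Fos and Igfbp5) kept their call in the alternatives that refitted them; the others lost it mostly with 1 library fewer. The 2-fold limit is apart from these, and leaves only Rtkn, Fos and LOC100910245. Deviations of same-numbered libraries correlated at -0.31, 0.28 and -0.03, so the replicate numbers gave no steady pairing. Differently numbered pairs ran from -0.34 (control replicate 3, PERK replicate 2) to 0.37 (control replicate 3, PERK replicate 1). Control replicate 1 and PERK replicate 3 correlated at 0.28. A shared batch or a pairing under other numbers was not tested and stays open. The replicate block calls are given for completeness. With an estimated correlation 0 gene lists passed; with the replicate block 7 did. With the preset correlation 6 of the 9 called lists kept their call in the 16 alternatives run on lists, and the eIF2 kinase, chaperone and matrix lists did not. The block gave adjusted p = 0.0530 for the kinases and 0.0755 for the chaperones. Without a filter and with the preset correlation 12 lists passed, with the mitochondrial unfolded protein response, tricarboxylic acid cycle and hypoxia lists added. Member counts moved too. With 1 library left out, members higher over all genes numbered 1 to 5 for sterol synthesis, 1 or 2 for immediate early genes and for ATF4 targets, 0 to 3 for heat shock and 0 to 2 for matrix genes. Over the list alone they numbered 16 to 19, 6 to 13, 9 to 15, 4 or 5 and 6 to 8, and 1 to 3 for tRNA synthetases and 2 to 5 for p53 targets. Cell cycle members lower over the list alone numbered 1 to 7. The robust fit gave 14 sterol, 6 ATF4 and 5 immediate early members over all genes, and the block 3, 1 and 1. Signs of values near 0 turned, and the cause was not tested. Ddit3 was 0.0029 without a filter and 3.1e-04 with counts divided by 6. The cytosolic ribosome median was -0.0017 with the replicate block, -0.0018 with DESeq2 size factors, -0.0018 with the stricter filter, -8.9e-04 with counts divided by 6 and -0.0016 without all-or-none genes; that of complexes II and III was -3.5e-04 with the stricter filter and -3.4e-04 with counts divided by 6. With 1 library left out, log2 fold changes ranged from -0.020 to 0.060 for Eif2ak3, -0.019 to 0.087 for Eif2ak4, -0.11 to 0.079 for Ddit3, -0.033 to 0.033 for Hsp90b1, -0.045 to 0.016 for Cox4i1, -0.0033 to 0.043 for Ifi27, -0.034 to 0.019 for Gabarap, -0.026 to 8.4e-04 for Idh2, -0.14 to 0.14 for Cd14 and -0.055 to 0.17 for Krt7. List medians ranged from -0.017 to 0.034 for complex I, -0.0092 to 0.060 for complexes II and III, -0.092 to 0.019 for mitochondrially encoded genes, -0.021 to 0.021 for the mitochondrial ribosome, -0.011 to 0.021 for the cytosolic ribosome, -0.013 to 0.020 for antioxidant genes, -0.13 to 0.013 for interferon genes, -0.0073 to 0.079 for p53 targets and -0.018 to 0.025 for autophagy. The alternatives on FPKM values were not run, because no FPKM column was matched to a library. Which entries depth limits was not tested, and the number of fragments behind a count is unknown.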

Other observations

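All tests below were chosen after the results were seen, except the tests on olfactory receptor genes and on overlapping genes. Lists of histone, actin cytoskeleton and fatty acid synthesis genes were made after seeing the changed genes, so the tests given are those of members that had not been called. Their adjusted p-values are over these added lists alone and cannot be set beside those of the 26 fixed lists. The 5 called cytoskeleton genes, among them Vcl, Actn1 and Actg1, were left out. The other 37 had a median log2 fold change of 0.106, and 34 lay above 0. With an estimated correlation camera gave them p = 0.0038 and adjusted p = 0.0114. The uncalled members thus lay higher as a group in the PERK-labelled libraries, on a list drawn up from these same data. Actins share reads with their copies. With Scd, Scd2, Fads1 and Fads3 left out, the other 15 fatty acid synthesis genes had a median of 0.127 and 13 lay above 0 (camera p = 0.0367 and adjusted p = 0.0551 with an estimated correlation). Among 30 uncalled histone genes 29 lay below 0, with a median of -0.388, but camera gave p = 0.186 with an estimated correlation of 0.592, so a fall of the family stays open.

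The real split of the 6 libraries gave 61 changed entries and the highest of the other 9 splits gave 5. The real split was thus the only 1 of 10 with as many, and 10 splits are too few for a share under 0.05.

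The first pattern is that Eif2ak3 was not higher in PERK-labelled libraries. A swap that hides a counted rise is argued against, since no control library exceeded 1.02 times the median level, but with an uncounted transgene this says nothing about whether the labels are right. A transgene whose reads are not counted under Eif2ak3 may account for it. The ATF4 target list had a median of 0.140, but heat shock and immediate early lists passed camera upward too, with the preset correlation. A PERK-specific response and a general stress response thus cannot be told apart. That no PERK was overexpressed at the RNA level also stays open, untested.

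The second pattern is that 80 entries were near 0 in some libraries and well expressed in others, Rtkn among them. The PERK group as the cause is argued against for most, since 95% of them (76) differ between libraries of 1 group. Among 10 entries with 3 libraries on and 3 off, 1 was split by group, Rtkn (10%, exact 95% interval 0.253% to 44.5%). Chance gives 10% too. The entries are too few to decide whether Rtkn follows PERK or falls by chance on the group split. The share also depends on the limits, as entries chosen after their values were seen show. Hmgb3 had 309, 973 and 914 counts in control replicates 1 to 3 and 0, 0 and 22 in PERK replicates 1 to 3. It splits by group, but its 22 counts are over 0.1 CPM. LOC100910245 splits too, but stays under 5 CPM. NEWGENE_1310561 and AABR07006049.2 are also left out by the 0.1 CPM limit, and do not split by group. Only 25 of the 80 entries could be placed on the reference, and 5 of these had an overlapping gene. Counts moved to an overlapping gene could be seen for 1 of the 5 (mean over reassigned libraries 0.183, permutation p = 0.144). Entries that could not be placed, and exchanges between copies of a gene that do not overlap, were not tested. In that one, Wbp11l1 stood at 4 and 3 counts in control replicates 1 and 3, where Wbp11 had 2355 and 1759, but PERK replicate 3 had 2210 and 1112, which a plain exchange does not give, so how the authors' counting assigned reads stays open.

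The third pattern is that control replicate 3 had 6839 entries at 0 against 9441 to 10749 elsewhere. Depth is argued against, since its total ranks 6 of 6, and so is a smaller count step, since the period of its low counts was 6.05 against 5.8 to 5.9. Olfactory receptor genes above 0 made up 45.4%, against at most 14.5% elsewhere, consistent with reads from outside expressed genes, such as genomic DNA, though this was tested on 1 library. Of 191 low-count entries lower in the authors' deposited table, control replicate 3 was the highest control in 144. No biological explanation was tested for this pattern.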
